A study of Homo sapiens with 20 samples.

How the data were processed

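Total RNA of 20 human lung tissue samples was measured on Agilent miRNA microarrays with 1 colour (Cy3), 1 array per sample. The sample titles put 10 samples in the usual interstitial pneumonia (UIP) group and 10 in the control group, and the groups were taken from those titles, because the description field carries the same wording for samples of both groups. Per the labels' protocols, the control tissue came from disease-free margins of lung cancer resections, and the labels call the samples of each group biological replicates, so the spread between arrays includes differences between donors.

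The deposited scanner files hold linear intensity values, and per the file headers they were made with Agilent Feature Extraction 9.5.3.1, with a spatial background fitted and subtracted within each array and no normalization between arrays. The other deposited columns used, quality flags of each spot and gene, were written by the authors' run of the same program. The authors' deposited value table holds the same background-subtracted intensity values to rounding, on a linear scale, uncentred and unscaled between arrays, and it was used as an alternative. Its column medians ran from 0.680 to 2.27 intensity units.

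Each file listed 12033 spots, of which 953 were controls and were left out. Spots with outlier flags, 2.22% to 6.71% of the non-control spots of an array, were left out as well, and no spot was saturated. The processed intensities of the remaining spots were averaged over the spots of each of 1510 probes. Each array was divided by the 75th percentile of its probe intensities over the 219 probes that were well above background on all 20 arrays. Scaled values under 10.4 were then set to that floor, the median over arrays of the lowest scaled signal of any probe well above background, and log2 was taken. The floor lies at 3.38 on the log2 scale, and values at it have no order. A miRNA was represented by its probe with the highest mean over all 20 arrays, a choice blind to group. A probe was well above background on an array when most of its used spots carried that flag. Of 470 human miRNAs on the array, the 184 whose chosen probe was well above background on at least 5 arrays of a group were tested. Of them, 157 had 2 or more probes well above background on at least 5 of the 20 arrays, whatever the group. These probes pointed in opposite directions for 16 miRNAs and for 0 of those past the threshold. Names are those of the array design, which are older miRBase names, and positions are those the files give on hg18. Of the 470 human miRNAs, all but 9 matched a miRNA gene by symbol or synonym in a RefSeq table for assembly GRCh38, which was used for names alone. Members of a miRNA family differ by few bases, so probes of close relatives such as the let-7, miR-30 and miR-199 miRNAs may read part of each other's signal.

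UIP and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over the 184 miRNAs and a threshold of 0.05. Fixed miRNA lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over 18 of the 25 lists, with an estimated correlation and limma's fry beside it. Counts of miRNAs detected per array, scores on the principal components (centred, not scaled) and distances to the group mean were compared with 2-sided permutation tests of 100000 resamples. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The design, the lists and all alternatives but those named below as added were fixed before the data were examined.

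Named in the text are up to 12 miRNAs with the largest rise and 12 with the largest fall among those past the threshold, 14 miRNAs known from work on fibrosis or as markers of cell types whatever their result, and from each list up to 4 tested members with the smallest p, or every member of a list of 5 or fewer.

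The alternatives tried were the percentile over all probes, quantile normalization, no scaling, normexp background correction with an offset of 50, no floor, the mean over the probes of a miRNA, the total gene signal of the files, the value table, no filter, a stricter filter, outlier spots kept, the slide as a block and each slide alone, the replicate number as a block, a variance trend, array weights and leaving out each array in turn. Blocks for the row and the column of the array on its slide, the comparison without 3 control arrays that shared a slide position, removal of a trend with probe length and a permutation test of every miRNA for the count were added after the data were seen.

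On simulated arrays with the means and spreads of the 184 miRNAs, 15 miRNAs were changed at each of 3 sizes in 20 simulations of the comparison of UIP with control. limma found 26.3% of changes of 0.5 on the log2 scale, 77.0% of changes of 1 and 94.0% of changes of 1.5, and 3.27% of its calls were false. Each miRNA was drawn independently from a normal distribution without a floor. These shares therefore need not hold for dim miRNAs or for miRNAs that vary together between arrays. The number of arrays limits the precision: the median miRNA had a 95% interval of ±0.52 on the log2 scale.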

Results

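miRNA levels were measured in lung tissue with usual interstitial pneumonia (UIP), the histological pattern of idiopathic pulmonary fibrosis, a progressive scarring disease of the lung, and in histologically normal control lung. There were 10 samples per group, 1 array each, on 3 slides that each held both groups. The summed processed intensity of an array ranged from 874849 to 2272780. Of 470 human miRNAs on the array, 179.5 ± 16.2 (SD, n = 10) were well above background in UIP and 163.8 ± 22.2 (SD, n = 10) in control, a difference of 15.7 that did not pass a 2-sided permutation test (p = 0.0909). The arrays lay at 7 positions of a slide, of which 3 held UIP arrays only, 3 held control arrays only and 1 held both, so position and group were confounded. The 3 control arrays at row 2, column 1 detected 138.7 ± 22.0 miRNAs, against 174.6 ± 11.1 on the other 7 control arrays.

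The comparison of the groups asks which miRNAs differ between fibrotic and normal lung. Of 184 tested miRNAs, 8 passed the threshold, 5 lower and 3 higher in UIP. The count depended on the setting: it was 7 to 19 when 1 array was left out, 20 with array weights (12 higher, 8 lower) and 1 with normexp. The fallen miRNAs were miR-338, miR-203, miR-126, miR-30b and miR-30d, and the raised ones were miR-127, miR-132 and miR-182. On the chosen probes all 8 differed by between 1.86-fold and 2.93-fold. Their second probes gave the same direction, with smaller log2 fold changes for miR-127 (0.72 against 1.54) and miR-182 (0.37 against 0.89). A further 31 miRNAs had an unadjusted p under 0.05 without passing the adjustment, and the 39 in all compare with 9.2 expected by chance.

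miR-126, the miRNA of endothelial cells that lies in an intron of EGFL7, fell by 1.12 on the log2 scale (SE 0.19, limma adjusted p = 0.000483), from 12.41 ± 0.30 in control to 11.30 ± 0.48 in UIP (SD, n = 10 each). It was below the control mean in 10 of 10 UIP samples, and its probe target lies on hg18 chromosome 9 from 138684927 to 138684946. miR-126* from the other arm of the same precursor had a log2 fold change of -0.94 (SE 0.35, adjusted p = 0.108). Both passed when adjusted over the list alone.

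The miR-30 family fell as a group in UIP: all 5 members had negative fold changes, with a median of -0.91 (camera adjusted p = 0.00128, and adjusted p = 0.0399 with an estimated correlation). Of these, 2 passed over all tested miRNAs, 4 when adjusted over the list alone. miR-30b fell by 1.08 (SE 0.25, limma adjusted p = 0.00955) and miR-30d by 1.02 (SE 0.21, limma adjusted p = 0.00406), each below the control mean in 9 of 10 UIP samples. They are neighbours on hg18 chromosome 8, from 135881995 to 135882010 and from 135886344 to 135886357. The other members, miR-30a-5p at -0.91, miR-30c at -0.45 and miR-30e-5p at -0.54, did not pass. With the slide column as a block miR-30a-5p passed (adjusted p = 0.0465), and without UIP replicate 4 miR-30a-5p and miR-30c did. The call of miR-30b ended without the 3 control arrays at row 2, column 1 (log2 fold change -0.98, adjusted p = 0.0983), with no scaling (-1.09, adjusted p = 0.0686) and with normexp (-0.84, adjusted p = 0.0568). The call of miR-30d ended with normexp (-0.82, adjusted p = 0.0622).

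miR-203, a miRNA of differentiating squamous epithelium, fell by 1.35 (SE 0.27, limma adjusted p = 0.00311), from 6.35 ± 0.36 to 5.0 ± 0.80 (SD, n = 10 each). Its target lies on hg18 chromosome 14 from 103653563 to 103653580. miR-338, which lies in an intron of AATK, fell by 1.55 (SE 0.34, limma adjusted p = 0.00574), with its target on hg18 chromosome 17 from 76714281 to 76714303. Each was below the control mean in 10 of 10 UIP samples, and miR-338 was well above background on 7 UIP arrays and 10 control arrays. Values of miR-338 lay at the floor of 3.38 on some UIP arrays, as did miR-203 in UIP replicate 6. The sizes of these falls therefore depend on the floor. With normexp both calls ended, with miR-338 at -0.58 (adjusted p = 0.711) and miR-203 at -0.70 (adjusted p = 0.366), where the median of all tested miRNAs was -0.21. In the list of squamous and basal epithelium the other 2 tested members went the other way without passing over all miRNAs. miR-205, a miRNA of basal cells, had a log2 fold change of 2.24 (SE 0.74, adjusted p = 0.0671) and passed with array weights (2.44, adjusted p = 0.0332). miR-31 was not well above background on any control array and was on 8 UIP arrays (adjusted p = 0.0568). With control values raised to each array's lowest signal well above background, it was 1.67-fold higher in UIP. That is not a lower bound, since some UIP values were themselves set up to the floor. It stood at -0.13 with normexp. It passed over all miRNAs with the total gene signal (2.54, adjusted p = 0.00700), quantile normalization, no scaling, the slide or the slide column as a block, the variance trend and the permutation test. Adjusted over the list alone all 3 passed, 2 higher and 1 lower, and the list did not pass as a set (camera adjusted p = 0.834).

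**Figure D1:**
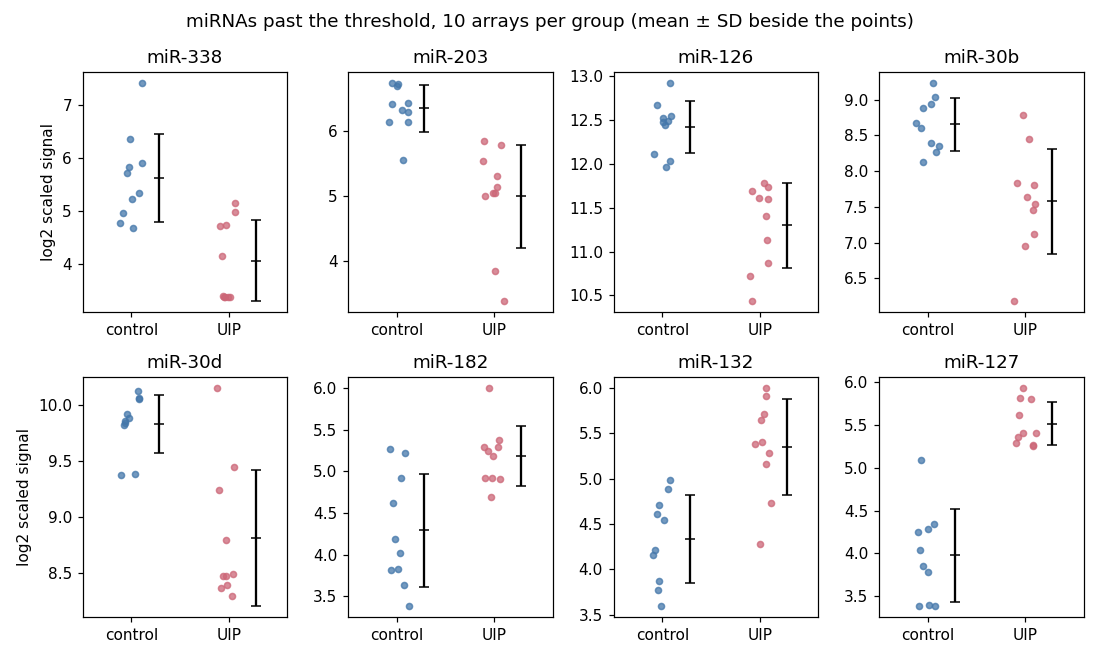
Log2 scaled signal (vertical axis) of the 8 miRNAs past the threshold on each array, with control and UIP side by side and the mean ± SD of 10 arrays as a bar. All UIP points of miR-126, miR-203 and miR-338 lie below the control mean, and all UIP points of miR-127 and miR-182 lie above it.

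The cluster at 14q32, an imprinted region with many miRNA genes, rose as a group in UIP. It had 7 tested members, of 50 on the array, with a median log2 fold change of 0.55 (camera adjusted p = 0.0111, and adjusted p = 0.0399 with an estimated correlation). The 6 that were well above background on at least 1 array of each group all had positive fold changes. The other, miR-299-5p, was not well above background on any control array. Its log2 fold change of 0.17 lay below the median, so raising its control values as for miR-31 could not move the median. miR-127 rose by 1.54 (SE 0.19, limma adjusted p = 1.68e-05), from 3.98 ± 0.54 to 5.52 ± 0.25 (SD, n = 10 each), and was above the control mean in 10 of 10 UIP samples. Its target lies on hg18 chromosome 14 from 100419129 to 100419146. The remaining 6 members did not pass over all miRNAs, with miR-376a at 0.76 (adjusted p = 0.0850) and miR-487b at 0.55, and miR-127 and miR-376a passed when adjusted over the list alone. miR-376a passed over all miRNAs with no floor (2.34, adjusted p = 0.0149), the total gene signal (1.81, adjusted p = 0.00700), array weights and the permutation test, miR-299-5p with the total gene signal (adjusted p = 0.0378) and miR-487b with array weights (adjusted p = 0.0341). In the main comparison miR-376a lay at the floor on 8 control arrays, so its size with no floor rests on signals under that floor. With normexp background correction 5 of the 7 members turned negative, the list was lost (adjusted p = 0.731) and miR-127 stood at -0.09 (0.12 above the median of all tested miRNAs), and 3 of the 7 members lay above that median. The offset makes up much of a dim signal in that setting, so these turns cannot show whether the dim members rose. Of the 7 members, 3 (miR-376a, miR-487b and miR-299-5p) passed the filter on dim probes through the UIP arrays only, so the filter favoured members higher in UIP. Besides miR-127, the members that passed it through both groups stood at 0.58, 0.22 and 0.02, and none of these passed over all miRNAs. The list was lost as well with no filter (adjusted p = 0.181) and with detection on all arrays of a group (adjusted p = 0.0550). With all probes in the percentile, which lowers all miRNAs nearly alike, 1 member was negative and all 7 lay above the median of all tested. With quantile normalization 1 was negative and 6 lay above it.

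The other raised miRNAs were dim as well. miR-132 rose by 1.02 (SE 0.23, limma adjusted p = 0.00589) and was above the control mean in 9 of 10 UIP samples, with its target on hg18 chromosome 17 from 1899973 to 1899988. miR-182 rose by 0.89 (SE 0.24, limma adjusted p = 0.0276) in 10 of 10 UIP samples, with its target on hg18 chromosome 7 from 129197525 to 129197542. Each of the 3 raised miRNAs was well above background on 10 UIP arrays and 7 control arrays. With normexp, miR-132 stood at -0.13 and miR-182 at -0.17 (0.075 and 0.039 above the median of all tested miRNAs), and of the 8 miRNAs miR-126 alone kept its call. Since the offset makes up much of a dim signal, these values cannot show whether the raised miRNAs changed. The call of miR-182 ended in 8 of the 20 comparisons that left out 1 array and in 8 of 20 other settings. Besides normexp these were all probes in the percentile (0.78), quantile normalization (0.76), no scaling (0.84), the total gene signal (0.90), no filter (0.89), the slide row as a block (0.87) and the comparison without the 3 control arrays at row 2, column 1 (0.80).

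miRNAs of smooth muscle and stromal cells rose as a group at the preset correlation (camera adjusted p = 0.00142), but not with an estimated one (adjusted p = 0.171 with an estimated correlation), and fry gave an adjusted p of 0.0103. All 14 members had positive fold changes with a median of 0.39, though 3 were negative with all probes in the percentile and 2 with normexp. In each of these settings all 14 lay above the median of all tested miRNAs. With normexp that median was -0.21, and the offset made up much of a dim signal. Lying above it therefore does not show a rise in that setting. None passed over all 184 miRNAs and 4 passed when adjusted over the list alone: miR-199a* at 0.60, miR-214 at 0.68, miR-199a at 0.52 and miR-199b at 0.99. The first 3 had an adjusted p of 0.0541 over all miRNAs and miR-199b 0.0653. With the slide as a block miR-199a* (0.64, adjusted p = 0.0126) and miR-199a (0.54, adjusted p = 0.0304) passed over all miRNAs. Both also passed with the mean over probes, the variance trend, array weights, the length trend removed and the permutation test. miR-214 passed with the mean over probes, the variance trend, array weights and the slide column as a block. miR-214 and miR-199a* passed with detection on all arrays of a group. miR-199b passed with array weights and the length trend removed. In the other settings with all 20 arrays these 4 did not pass. The abundant smooth muscle miRNA miR-145 differed by 0.06 (SE 0.31, adjusted p = 0.956).

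**Figure D2:**
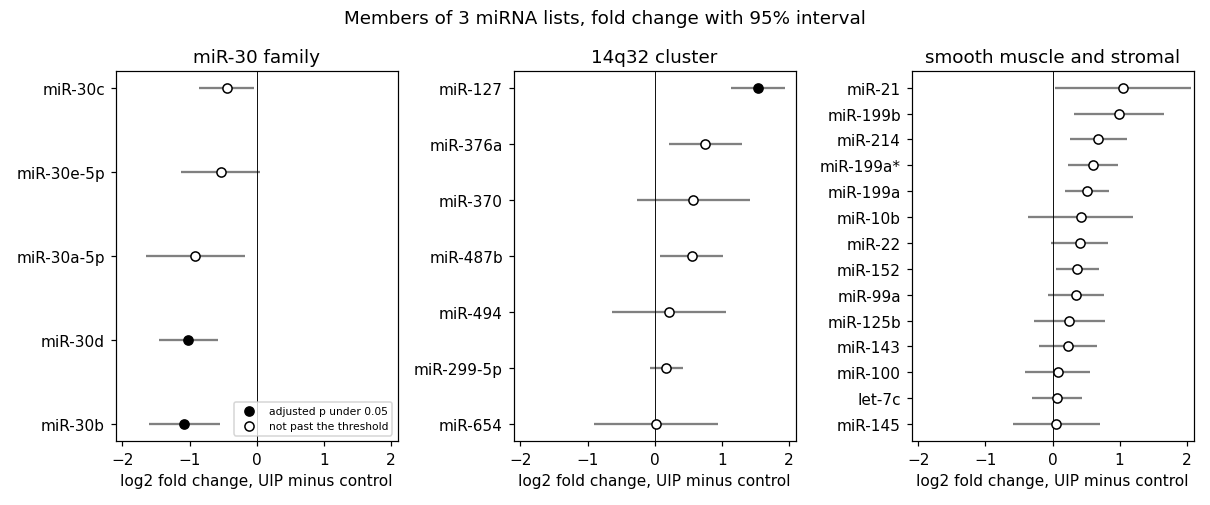
Log2 fold change of UIP minus control (horizontal axis) with its 95% interval for the tested members of 3 lists, filled where the adjusted p over all 184 miRNAs was under 0.05. The 5 members of the miR-30 family lie below 0, and the 7 members of the 14q32 cluster and 14 of the stromal list lie above 0. With normexp 5 of the 14q32 members and 2 of the stromal members turned negative, and with all probes in the percentile 1 and 3 did. All 14 stromal members lay above the median of all tested miRNAs in both settings, as did all 7 of the 14q32 cluster with the percentile and 3 of them with normexp. The normexp offset makes up much of a dim signal, so lying above the median in that setting does not show a rise. Control values lay at the floor on 10 arrays for miR-299-5p, 8 for miR-376a and 7 for miR-487b, so the size of these 3 depends on the floor.

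Of 19 tested miRNAs from reports on TGF-beta and fibrosis, none passed over all miRNAs and 2 passed when adjusted over the list alone, miR-199a upward and miR-26a downward (log2 fold change -0.41, SE 0.13, adjusted p over all miRNAs 0.0568). miR-26a passed over all miRNAs with the permutation test (adjusted p = 0.0129), the mean over probes (0.0379), the total gene signal (0.0424) and no filter (0.0464). let-7d had a log2 fold change of -0.41 (SE 0.18, adjusted p = 0.197), and miR-21, the profibrotic miRNA most often named, 1.05 (SE 0.49, adjusted p = 0.218), higher than the control mean in 8 of 10 UIP samples. miR-155 stood at 0.48 (adjusted p = 0.226) and miR-29c at -0.37 (SE 0.34, adjusted p = 0.582). miR-154 was not tested, since it was well above background on 3 UIP arrays and 0 control arrays. The miR-29 family (3 tested) and the miR-26 family (2 tested, miR-26b at -0.40) had 0 members past the threshold over all miRNAs, and miR-26a passed when adjusted over its list alone.

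Markers of other cell types did not pass. Of 5 tested members of the epithelial miR-200 family none passed, and miR-200c stood at -0.27 (SE 0.26, adjusted p = 0.582). The ciliated cell miRNAs miR-449, miR-34b and miR-34c stood at 1.0, 0.67 and 0.61 with SEs of 0.57, 0.56 and 0.58, and miR-449b was not well above background on any array. Of 12 tested miRNAs of myeloid and lymphoid cells none passed, with the myeloid miR-223 at -0.24 (SE 0.32) and the lymphocyte miR-150 at -0.31 (SE 0.29). Of the 3 tested red blood cell miRNAs none passed, with miR-451 at 0.46 (SE 0.39), and of 3 tested striated muscle miRNAs none passed, with miR-133a at 0.33 (SE 0.30).

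In the other lists none passed over all miRNAs. The let-7 family (9 tested) had a median of -0.22, with let-7f at -0.37, and the cluster from miR-17 to miR-92 and its paralogs (13 tested) had a median of -0.23, with miR-92 at -0.58 (SE 0.21). The p53 and senescence list had 7 tested members and a median of 0.41, with miR-34a at 0.41. The hypoxia list (9 tested, miR-210 at -0.14) and the family of miR-15, miR-16, miR-195 and miR-497 (6 tested, miR-15b at -0.51) had medians and means of opposite sign near 0, and 2 members of the hypoxia list passed when adjusted over it alone, 1 higher and 1 lower. The miR-23/27/24 clusters (5 tested, miR-27b at 0.32) and the miR-99/100 and miR-125 family (5 tested, miR-125a at -0.46) did not pass either. With normexp the p53 and senescence list (adjusted p = 0.00924) and the miR-23/27/24 clusters (adjusted p = 0.0263) passed camera upward. Camera sets a list against the other tested miRNAs, and the median of all tested was -0.21 with normexp. These 2 passes therefore do not show that the members rose. Over the 15 lists that did not pass camera, the lowest adjusted p was 0.235, of the list of miR-17 to miR-92. Of lists too small for the test, the miR-221 and miR-222 cluster had miR-222 at -0.42 and miR-221 at 0.04, the HOX cluster miRNAs had miR-10b at 0.42 and miR-10a at -0.24, the Xq26 list had miR-424 at 0.10, the list of other tissues had miR-375 at -0.78 (adjusted p = 0.141, passing over the list alone) and miR-128a at 0.02, and the placental cluster had miR-518c* at 0.09.

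Within slides the comparison rests on 3 or 4 arrays per group, and limma called 0 miRNAs on each slide, with 21, 19 and 20 miRNAs at an unadjusted p under 0.05. The 8 miRNAs past the threshold kept their direction on each of the 3 slides, and with the slide as a block all 8 stayed past the threshold among 11 calls. The 3 added calls were miR-199a*, miR-199a and miR-31 (adjusted p = 0.0372), each higher in UIP.

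The first principal component held 29.1% of the spread between arrays and did not separate the groups, with mean scores of 0.88 ± 5.51 in UIP and -0.88 ± 5.05 in control (SD, n = 10 each, permutation p = 0.465). The groups differed on the second component, which held 19% of the spread (UIP minus control -4.17, permutation p = 0.0239), and on the third, which held 14.1% (UIP minus control -4.16, permutation p = 0.00672). The tests of these 2 components were added to the test of the first after the data were seen, and their p values are unadjusted. Samples lay 9.13 ± 1.66 log2 units from their own group mean in UIP and 8.26 ± 1.36 in control (SD, n = 10 each), a difference of 0.87 that did not pass (permutation p = 0.215), and with normexp the difference was -3.20 (permutation p = 0.0181).

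**Figure D3:**
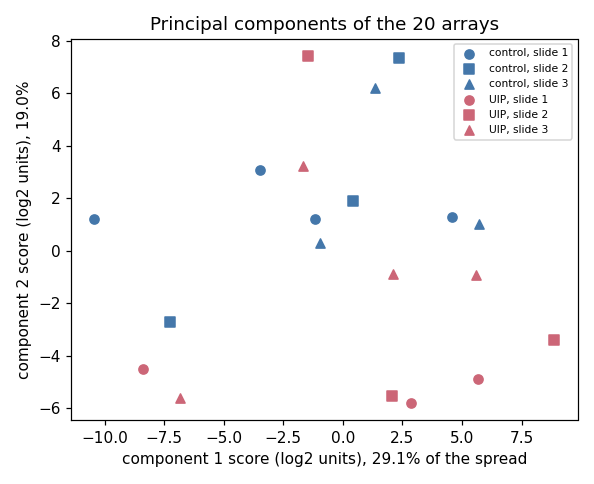
Scores of the 20 arrays on the first (horizontal axis, log2 units, 29.1% of the spread) and second (vertical axis, log2 units, 19%) principal components, with colour for the group and shape for the slide. UIP and control points overlap along the first component, and along the second the mean of the UIP points lies lower (permutation p = 0.0239).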

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

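Each miRNA named in the text and 3 measures of each array were searched, group by group, for a single sample with a gap to its nearest neighbour that was large against the range of its group. Of 159 groups whose values were not all at the floor, 11 held such a sample. Chance gives about 7.95 for normal values, a count that does not hold for groups largely at the floor. The value in each case is the gap as a share of the group's range, followed by the log2 level of the sample and the mean ± SD of the other 9.

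In UIP, replicate 3 stood apart for let-7g (0.517, at 10.90 against 9.87 ± 0.22), for miR-182 (0.473, at 6.0 against 5.09 ± 0.24) and for miR-128a (0.882, at 3.55, with the others at or next to the floor of 3.38). UIP replicate 6 stood apart for miR-92 (0.483, at 10.91 against 9.66 ± 0.33).

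In control, replicate 6 stood apart for the ciliated cell miRNA miR-449 (0.632, at 6.80 against 3.58 ± 0.43, most of these at the floor) and for miR-376a (0.640, at 3.62 against 3.39 ± 0.03, close to the floor). Control replicate 5 stood apart for miR-1 (0.637, at 4.51 against 3.45 ± 0.14, most of these at the floor) and for miR-375 (0.482, at 5.47 against 6.94 ± 0.36). Control replicate 1 had the lowest miR-203 (0.492, at 5.56 against 6.44 ± 0.24), control replicate 7 the lowest miR-34b (0.469, at 3.47 against 6.57 ± 0.81) and control replicate 4 the highest miR-17-3p (0.506, at 4.66 against 3.96 ± 0.14).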

How the results depend on the processing

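The added alternatives, which are the row and column of the slide as a block, the comparison without the 3 control arrays at row 2, column 1, the removal of the probe length trend and the permutation test for the count, were chosen after the data were seen.

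The fall of miR-126 stayed past the threshold in every alternative with all 3 slides, and miR-203, miR-338 and miR-30d and the rises of miR-127 and miR-132 stayed in all of these but normexp. miR-30b was lost with normexp, with no scaling and without the 3 control arrays at row 2, column 1. miR-182 was lost most often, in 8 of 20 settings: with all probes in the percentile (adjusted p = 0.105), quantile normalization (0.0972), no scaling (0.186), normexp (0.780), the total gene signal (0.0582), no filter (0.0736), the slide row as a block (0.0569) and without those 3 arrays (0.104), while its log2 fold change ran from 0.63 to 0.94 in the settings other than normexp. The number of miRNAs past the threshold was 8 and ranged from 6 to 12 in most alternatives. It was 1 with normexp (0 higher, 1 lower), 20 with array weights (12 higher, 8 lower) and 13 with the permutation test, and 0 on slide 1, slide 2 and slide 3 alone, where fewer arrays were compared. The number higher in UIP was 6 with the mean over probes, 5 with the total gene signal, 5 with detection on all arrays of a group, 6 with the slide as a block, 7 with the variance trend, 5 with the slide column as a block and 6 with the probe length trend removed, and the cause was not tested. Leaving out 1 array gave 7 to 19 miRNAs, with 2 to 10 higher and 5 to 9 lower. The 19 came without UIP replicate 4 and 18 without UIP replicate 10, and the cause was not tested. With the replicate number as a block 9 miRNAs passed, 4 of them higher, with miR-205 added (adjusted p = 0.00909), and 3 lists. Nothing in the labels says that the replicate numbers pair the samples, and the control tissue came from margins of lung cancer resections. The correlations of pairs with the same number ran from -0.49 to 0.62, and 3 of 10 UIP samples correlated best with their own number. These correlations do not decide whether the numbers pair.

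The lists kept 3 calls in every comparison that left out 1 array. There were 5 list calls on slide 1, with the ciliated, striated muscle and p53 lists added, and 0 on slide 2. With normexp 4 lists passed, with the p53 and senescence list (adjusted p = 0.00924) and the miR-23/27/24 clusters (adjusted p = 0.0263) added. The 14q32 cluster was lost with normexp (camera p = 0.528, adjusted 0.731), with no filter (p = 0.0494, adjusted 0.181), with detection on all arrays of a group (p = 0.0110, adjusted 0.0550), on slide 1 (p = 0.0602) and on slide 2 (p = 0.0288, adjusted 0.130). The stromal list was lost with an estimated correlation (p = 0.0285, adjusted 0.171), on slide 2 (p = 0.149) and on slide 3 (p = 0.0499, adjusted 0.235), and the miR-30 family on slide 2 (p = 0.0139, adjusted 0.130). Apart from the slides, where fewer arrays were compared, the cause was not tested.

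The difference in detected miRNAs ran from 11.4 to 18.4 when 1 array was left out, and passed without UIP replicate 5 (p = 0.0497). The difference in spread within groups turned to -3.20 with normexp (permutation p = 0.0181). The difference in the first component turned to -0.30 with miRNAs detected on all 20 arrays (permutation p = 0.868) and to -0.079 with unit variance (permutation p = 0.980). It ran from -0.73 to 3.75 when 1 array was left out. The sign of a component is arbitrary, so these turns do not show a reversal.

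Of the named miRNAs, those past the threshold kept their sign in every alternative but normexp, and the others that turned are given with their log2 fold change. With all probes in the percentile, miR-145 -0.043, miR-200b -0.055, miR-16 -0.041, miR-27a -0.086, miR-221 -0.062 and miR-100 -0.020. With quantile normalization, miR-200b -0.13, miR-424 -0.0063, miR-23a 0.050, miR-27a -0.013 and miR-221 -0.089. With no scaling, miR-27a -4.41e-05. With normexp, miR-127 -0.090, miR-132 -0.13, miR-182 -0.17, miR-200b -0.0086, miR-429 -0.22, miR-449 -0.0035, miR-31 -0.13, miR-376a -0.26, miR-487b -0.28, miR-299-5p -0.33, miR-133a -0.20, miR-1 -0.33, miR-133b -0.14, miR-486 -0.092, miR-497 -0.10, miR-424 -0.23, miR-23a 0.079, miR-27a -0.0017, miR-221 -0.10, miR-10b -0.021, miR-128a -0.35 and miR-518c* -0.34. With no floor, miR-1 -0.67. With the mean over probes, miR-141 0.077. With the total gene signal, miR-145 -0.034, miR-200b -0.028, miR-16 -0.049, miR-27a -0.089, miR-221 -0.039 and miR-100 -0.024. With the slide as a block, miR-200a 0.025 and miR-141 0.061. With array weights, miR-223 0.054, miR-145 -0.069, miR-486 -0.38, miR-23a 0.0067 and miR-27a -0.034. With the slide row as a block, miR-223 0.027, miR-16 -0.021, miR-27a -0.13 and miR-221 -0.0085. Without the 3 control arrays at row 2, column 1, miR-145 -0.21, miR-29a 0.024, miR-29b 0.056, miR-200a 0.13, miR-200b -0.038, miR-141 0.30, miR-133b -0.014, miR-486 -0.27, miR-23b -0.020, miR-99b 0.055 and miR-100 -0.066. With the probe length trend removed, miR-486 -0.028 and miR-27a -0.076. On slide 1 alone, miR-451 -0.45, let-7f 0.0064, let-7a 0.046, miR-200a 0.14, miR-486 -1.10, miR-16 -0.53, miR-195 0.14, miR-23a 0.073, miR-221 -0.012 and miR-10a 0.11. On slide 2 alone, miR-200c 0.54, miR-200a 0.10, miR-133a -0.20, miR-1 -0.51, miR-133b -0.35, miR-150 0.12, miR-181a 0.070, miR-424 -0.80, miR-34a -0.30, miR-210 0.32, miR-23a 0.29, miR-27a -0.31, miR-99b 0.48, miR-100 -0.086, miR-375 0.47 and miR-518c* -0.12. On slide 3 alone, miR-29c 0.21, miR-223 0.14, miR-145 -0.45, miR-34c -0.12, miR-29b 0.71, miR-200b -0.78, miR-141 0.58, miR-34b -0.0053, miR-20a 0.15, miR-19b 0.23, miR-133b -0.012, miR-195 0.18, miR-23b -0.20, miR-221 -0.15, miR-99a -0.087, miR-100 -0.13, miR-125b -0.23 and miR-10b -0.046. When 1 array was left out, the range crossed 0 for miR-100 from -0.035 to 0.20, miR-141 from -0.32 to 0.30, miR-145 from -0.076 to 0.20, miR-16 from -0.059 to 0.17, miR-200a from -0.18 to 0.092, miR-200b from -0.12 to 0.19, miR-221 from -0.023 to 0.10, miR-23a from -0.087 to 0.064, miR-27a from -0.12 to 0.12, miR-29b from -0.53 to 0.11, miR-486 from -0.14 to 0.32 and miR-99b from -0.14 to 0.10. For these turns the cause was not tested.

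Signal over background limits the dim miRNAs: miR-127, miR-132 and miR-182 were well above background on 7 of 10 control arrays. Their calls were lost with the background correction that adds an offset. That correction also ended the calls of miR-203, miR-338, miR-30b and miR-30d. The last 2 were well above background on all 20 arrays, so dimness alone does not set the lost calls apart.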

Other observations

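The array also carries probes for 64 viral miRNAs, of which 8 were well above background on at least 5 arrays of a group and 3 were on all 20 arrays of both groups, while 54 were on no array. None passed between UIP and control in limma, and 1 had an unadjusted p under 0.05, hsv1-miR-H1 with a log2 fold change of 0.93 (SE 0.32, adjusted p = 0.0622). The brightest, ebv-miR-BART19, stood at 10.26 ± 1.03 in UIP and 9.92 ± 0.76 in control (SD, n = 10 each, adjusted p = 0.403). These values do not show which RNA bound the probes. Of 38 positive control probes, 0 passed in limma and 0 had an unadjusted p under 0.05.

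The slide row and column as blocks, and the tests of slide and total signal on the first component, were chosen only after the result was seen, and the bound for the slide as a block, an alternative fixed beforehand, was also set after it. For the 8 miRNAs past the threshold between UIP and control, of 100 splits of the 20 arrays, 1, the real one, gave as many as 8 miRNAs and the highest of the others gave 5, which argues against chance. Each slide held 3 or 4 arrays of each group, so differences between slides could hardly have produced them. All 8 stayed past the threshold with the slide as a block and kept their sign on each slide. All 8 stayed after each array's trend with probe length was removed, so that trend does not account for all of them. Whether its removal takes out an effect between a shorter and a longer probe of the same miRNA was not tested. The ratio of such probes followed the first component (rho -0.623), while probe length over the miRNAs did not follow its loadings (rho -0.0911). An effect of that kind is therefore not set aside. The position of the array on the slide cannot be told apart from the groups, since 1 of 7 positions held both, and the row as a block, with which 7 stayed, or the column, with which all 8 stayed, sets only 1 of the directions aside. The background correction stays open as well. With normexp, which took the median of all tested miRNAs to -0.21, miR-126 alone stayed past the threshold. The 3 raised miRNAs lay 0.12, 0.075 and 0.039 above that median. The others lay below it, with miR-338 at -0.38, miR-203 at -0.49, miR-30b at -0.63 and miR-30d at -0.61 from it. The offset of 50 was added before scaling, so it makes up much of a dim signal, whose difference then follows the scaling of the arrays. miR-128a, miR-518c* and miR-1, at the floor on most arrays, stood at -0.35, -0.34 and -0.33 with normexp, against 0.02, 0.09 and 0.17 in the main comparison. Normexp therefore cannot tell whether the 3 dim raised miRNAs changed. In UIP, miR-338 at 4.07 and miR-203 at 5.0 on the log2 scale were dim as well. The same limit holds for their distances from the median of all tested miRNAs. Differences between the donors of the groups other than the disease were not tested.

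The largest direction of spread between arrays did not follow the groups. Slide accounted for 0.0451 of the spread of the scores (permutation p = 0.673) and total signal had a Spearman's rho of 0.0647 with them (permutation p = 0.788), which argues against both. A candidate explanation is hybridisation or labelling that depends on probe length: the median ratio of a shorter to a longer probe of the same miRNA, over 84 miRNAs, followed the scores with a Spearman's rho of -0.623 (permutation p = 0.00383, 0.0115 adjusted over 3 tests) and a Pearson's r of -0.557 (permutation p = 0.0111). The r stayed at -0.51 without the 2 arrays farthest from the median ratio. As rho it was -0.75, -0.60 and -0.93 within the slides, and -0.84 within UIP but -0.43 within control. Over the miRNAs themselves, which are not independent, probe length did not follow the loadings (rho -0.0911, permutation p = 0.217), so it may be part of the cause only, and differences between donors were not tested.

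The miR-30 family fell while stromal miRNAs rose in camera at the preset correlation and in fry (adjusted p = 0.0103) but not with an estimated correlation (adjusted p = 0.171), and a hypothesis is that a shift between epithelial or endothelial and stromal cells in the tissue may lie behind both. With group means removed, the means of both lists had a Spearman's rho of -0.310 over 20 arrays (permutation p = 0.185) and a Pearson's r of -0.557 (permutation p = 0.0112). The r fell to -0.20 without the 2 arrays farthest from the median of the stromal mean, so it rests on those samples. Within the slides rho was -0.21, -0.49 and -0.50, but it was -0.55 within UIP and 0.067 within control, and over all arrays it was -0.153 (permutation p = 0.516) after the probe length trend was removed. The test left this open, with too few arrays to tell the value from 0: the endothelial miR-126 fell by 1.12 (adjusted p = 0.000483), with miR-126* at -0.94, while miR-145 and the miR-200 family, abundant in smooth muscle and epithelium, did not pass between the groups.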
